A study of Mus musculus with 6 samples.

How the data were processed

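RNA-seq had been done on primary somatosensory cortex of 14-day-old C57BL/6 mice, with 3 libraries from mice carrying a floxed exon 3 of Ctnnb1 (control) and 3 from mice that also carried Nex-Cre (overexpression). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. Bowtie2 2.0.6 and TopHat2 2.0.9 are named in the submitters' processing notes. The genome build, the annotation, the read counter, the strand setting and the differential test are not given in the sources used here. The labels number the replicates but do not say that each came from a separate animal, so p-values measure only the spread between these samples, which may be technical in part.

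The only file used was a table of 47794 genes, of which 47069 had Ensembl IDs and 725 had IDs of unannotated transcripts. A symbol was found for 46488 of the Ensembl IDs, which is 98.8%. For each gene the authors deposited 1 signal value per group, the mean over libraries of read counts divided by a scaling factor per library, as read from the values. Per the file headers, the table also held the authors' log2 fold change, a p-value and an adjusted p-value. The deposited log2 fold changes differed from log2 of the ratio of the group means by at most 4.99e-05. The deposited adjusted p-values differed from Benjamini-Hochberg values of the deposited p-values by at most 0.00025. A spreadsheet error stood in place of minus infinity where the overexpression mean was 0. The group means summed to 18602579 in overexpression and 19016749 in control cortex. Group means carry no SD or n, and none is given for them.

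The tests were fixed before the data were examined. Because the table held only group values, genes were called by the authors' deposited adjusted p under 0.05. Gene-level fold changes were recomputed as log2 of the overexpression mean over the control mean. The 33 gene lists, with 1116 distinct genes of which 1102 were measured, were also fixed before the data were examined. For each list the number of genes past the threshold over all genes and adjusted over the list alone, the median log2 fold change and its percentile among 10000 random lists were computed. In the main setting medians and percentiles left out members listed at 0 in either group. Random lists had the same size and were drawn from the 100 genes on each side in mean expression. A list was called outside the random range below percentile 2.5 or above percentile 97.5. The two-sided share of random lists as far out was also adjusted over the 33 lists by the Benjamini-Hochberg method. The planned Fisher's exact test on the authors' calls was void with 0 calls, and was run on the share of genes with an authors' p under 0.05 in its place. Named genes were Ctnnb1 and Neurod6, the 12 genes with the largest increase and the 12 with the largest decrease among called genes, of which there were none, and in each list without a call the 2 members with the highest mean; some of these are not reported here. All other named genes were chosen after their values were seen.

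Alternatives foreseen for tables with a value per library could not be run on the table as deposited. Library values were therefore recovered from the group means, which was decided after seeing the data. The lowest values of each column took 3 sizes, the worth of 1 read in each library, and each group mean was matched to whole reads of 3 libraries within its rounding to 10 significant digits. Exactly 1 combination fitted 99.96% of 23575 control means up to 1000, and 99.38% of 21300 overexpression means up to 450. Above 500 in control and 100 in overexpression cortex, only library values within 2-fold of the group mean were searched. The recovered libraries are called A, B and C in order of scaling factor, and none can be tied to a replicate number. The scaling factors, which follow relative depth, were 0.982, 0.926 and 0.907 in control and 1.23, 1.06 and 0.966 in overexpression libraries. Both groups were recovered for 9781 genes with a mean of at least 10, which is 57.2% of such genes, and highly expressed genes such as Ctnnb1 and Neurod6 were not among them. limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend to log2 of the recovered value plus 1, so fold changes of low genes are understated. Lists with 5 or more recovered members were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, and with fry. Of the 13 lists outside the random range, the glutamatergic synapse, oxidative phosphorylation and sex-linked lists had fewer and were not tested so.

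The recovery, the limma fit and the random lists were tested on simulated data, and the other tests were not. In group means simulated for the control libraries, 99.97% of 22408 values had 1 combination, and 100% of those were right. In means simulated for the overexpression libraries, 99.2% of 20151 values had 1 combination, and 100% of those were right. The simulated library values were drawn with little spread within a group. Genes whose libraries lie beyond the 2-fold limit of the search were thus hardly tested. In a simulation of overexpression against control over 9781 genes, limma called 46.7% of genes changed by 1.5-fold, 86.7% of those changed by 2-fold and 94.0% of those changed by 4-fold. Of the unchanged genes in that simulation 6 were called. Its libraries were drawn independently with a spread set by expression level, so variation shared by many genes of a library was not simulated. Among its unchanged genes 4.66% had an unadjusted limma p under 0.05, against 2.12% of all genes in the fit to the recovered libraries. The simulated shares may thus overstate what could be called in these data. With fold changes shuffled between genes of similar level, 3.79% of lists lay outside the random range, and a glutamatergic synapse list shifted by -0.1 on the log2 scale lay below it in all 20 runs.

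The alternatives were a filter on mean expression, a threshold of 0.01, a minimum log2 fold change of 1, recomputed adjustment, centring on the median gene, pseudocounts of 0, 1 and 10, the mean in place of the median of a list, and the fits on recovered libraries. The reference annotation was used for gene names, exon lengths and which genes neighbour each other, and no coordinates are given because the authors' build is not known. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and numba 0.67.0 were used.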

Results

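The effect of stabilised β-catenin in excitatory neurons on the cortical transcriptome was examined by RNA-seq of primary somatosensory cortex from 14-day-old mice. β-Catenin, encoded by Ctnnb1, joins cadherins to the cytoskeleton and carries canonical Wnt signals to the nucleus. Removal of exon 3 takes away the sites that mark the protein for degradation, and Nex-Cre, expressed from the Neurod6 locus, recombines in excitatory neurons of the forebrain. The 6 libraries fell into 2 groups of 3, cortex with the floxed allele alone (control) and cortex with the floxed allele and Nex-Cre (overexpression). The deposited values were 1 mean scaled read count per gene and group, with no spread between replicates. Of 47794 genes, 17642 were listed at 0 in both groups and 30152 had been tested by the authors.

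No gene passed the threshold in either direction. In the authors' deposited table, 0 genes were higher and 0 were lower in overexpression cortex at an adjusted p under 0.05. The smallest adjusted p in the authors' deposited table was 0.135, for Gm3279, and the next was 0.76, for Neurod6. All other genes had an adjusted p of 1 in the authors' deposited table. The unadjusted p was under 0.05 for 161 genes in the authors' deposited table, 99 higher and 62 lower in overexpression cortex. These were 0.534% of tested genes, where p-values spread evenly would give 1508 genes. The share was 0.567% among genes with a mean of at least 100, so the shortfall was not confined to low genes. The median p of the authors' test was 0.725 over all tested genes. These p-values thus ran larger than evenly spread ones, and a lack of calls does not show that no gene changed. Of 11645 genes with a mean of at least 100, 97.3% had group means within 1.2-fold of each other, and 11 differed by 1.5-fold or more. On library values recovered from the group means for 9781 genes with a mean of at least 10, limma called 0 genes at an adjusted p under 0.05 and gave 207 genes with an unadjusted p under 0.05. With 1 library left out, the number with an unadjusted p under 0.05 ranged from 150 without control A to 368 without control C. The median 95% interval of a fold change reached 1.23-fold to either side for the 4335 recovered genes with a mean of at least 100.

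Ctnnb1 (ENSMUSG00000006932) had a mean of 6391 in overexpression and 7574 in control cortex. In the authors' deposited table this was a log2 fold change of -0.25 with p = 0.0304 and an adjusted p of 1. A gene-level value counts the exons outside the removed exon 3 as well, so it does not check the genotype labels. Neurod6 (ENSMUSG00000037984), a transcription factor gene of excitatory neurons whose locus carries Nex-Cre, had a mean of 1199 in overexpression and 1942 in control cortex. Its log2 fold change was -0.70, with p = 5.04e-05 and an adjusted p of 0.76, in the authors' deposited table. Adjusted over the list alone, among 16 general excitatory neuron markers, Neurod6 had p = 0.000806, again from the p-values of the authors' deposited table. No member of the other 32 lists passed when adjusted over the list alone.

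**Figure D1:**
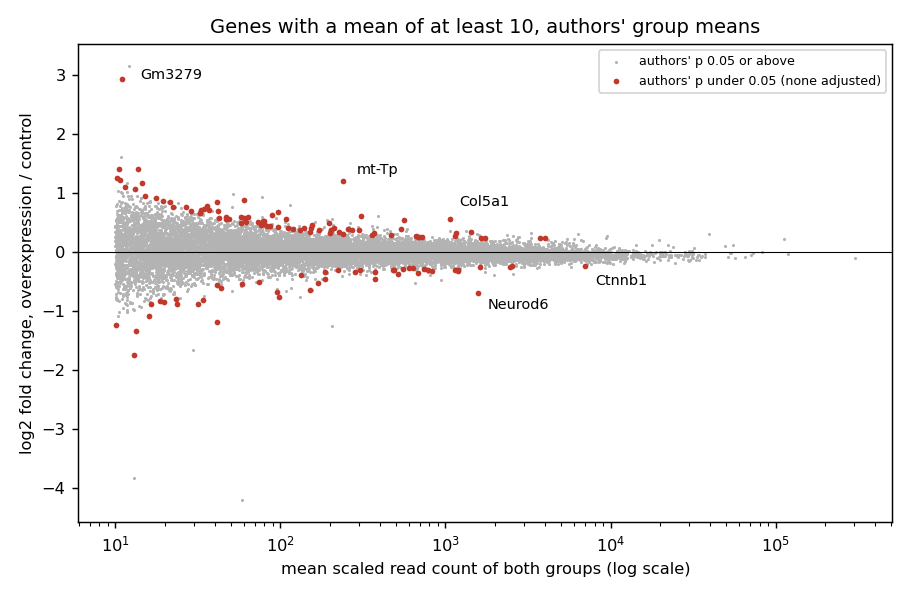
Log2 fold change of overexpression over control group means against the mean scaled read count of both groups (log scale), for genes with a mean of at least 10. Each point is 1 gene, red points had an unadjusted p under 0.05 in the authors' deposited table, and none passed after adjustment; Neurod6 lies at -0.70 and Gm3279 at 2.93.

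Several further genes had small unadjusted p-values, and they are named here after their values were seen. Gm3279, a long intergenic RNA gene annotated next to Neurod6, had a mean of 19.3 in overexpression and 2.53 in control cortex, with p = 4.49e-06 in the authors' deposited table. Its recovered library values were 19.3 ± 5.31 (SD, n = 3) in overexpression and 2.53 ± 1.73 (SD, n = 3) in control cortex. The fibrillar collagen genes Col5a1 and Col11a1 had log2 fold changes of 0.55 and 0.54 and unadjusted p of 0.000327 and 0.00555 in the authors' deposited table. Control library A stood apart for both genes. Its recovered values were 640 against 972 and 966 in control B and C for Col5a1, and 319 against 541 and 518 for Col11a1. Cplx3, a complexin gene, and Nxph4, a neurexophilin gene, both markers of the deepest cortical neurons, had log2 fold changes of 0.38 and 0.62 in the authors' deposited table. The list of 24 deep-layer markers had 12 higher and 12 lower members. Slc17a6, which encodes a vesicular glutamate transporter, had a mean of 448 in overexpression and 584 in control cortex. The mitochondrial proline tRNA gene mt-Tp had recovered values of 335 ± 124 (SD, n = 3) in overexpression and 146 ± 14.1 (SD, n = 3) in control cortex. None of these genes passed adjustment in the authors' deposited table.

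**Figure D2:**
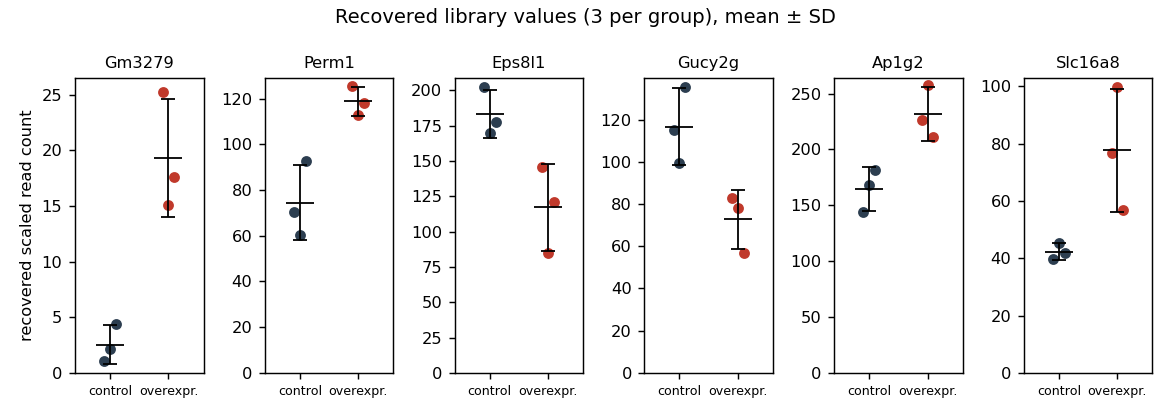
Recovered scaled read counts of each library (points, 3 per group) with mean and SD (bars), for the 6 genes with a symbol and the smallest unadjusted p in the authors' deposited table whose values were recovered in all 6 libraries. The y axes start at 0, and Gm3279 has 19.3 ± 5.31 in overexpression against 2.53 ± 1.73 in control cortex.

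Genes known as direct targets of canonical Wnt signalling gave no call by the authors' test. Of 29 measured targets 0 passed the threshold and 0 had an unadjusted p under 0.05 in the authors' deposited table. Among all tested genes only 0.534% had an unadjusted p under 0.05 there. A count of 0 among 29 was thus likely in advance and does not show that the targets were unchanged. Their median log2 fold change was -0.01, at percentile 40.1 of random lists, with 13 genes higher and 16 lower, and it was 0.03 over members with a mean of at least 10, while the mean over all 29 was -0.083. Tnfrsf19 was at 1728 in overexpression and 1832 in control cortex, and Apcdd1 at 1525 and 1396. Widely used targets, named here after their values were seen, had similar means, with Axin2 at 462 and 484, Lef1 at 104 and 101, and Nkd1 at 364 and 352. The median of 56 Wnt ligands, receptors and signalling components was -0.03, at percentile 18.2, with Apc at 23118 and 21229 and Gsk3b at 6072 and 6246. Of these 56 genes, 2 had an unadjusted p under 0.05 in the authors' deposited table, Dvl2 with a higher and Wnt16 with a lower mean in overexpression cortex, both named after their values were seen (Fisher's exact p = 0.277 adjusted over the 33 lists). Among 32 genes of the cadherin-catenin adhesion complex, 0 passed the threshold and the median was -0.045, at percentile 10.4. Of these 32 genes, 4 had an unadjusted p under 0.05 in the authors' deposited table, namely Ctnnb1, Cdh8 and Cdh22 with lower and Cdh24 with higher means in overexpression cortex, the 3 cadherins being named after their values were seen. That share was larger than among other genes by a two-sided Fisher's exact test, which treats genes as independent, with p = 0.000706 adjusted over the 33 lists. On 8 recovered members the adjusted p was 0.781 by camera with an estimated correlation. Ctnnd2, which encodes δ-catenin, was at 5499 in overexpression and 5786 in control cortex.

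Several lists of neuronal genes had medians slightly below those of random lists, although 0 of their members passed the threshold. For 52 glutamatergic synapse genes the median log2 fold change was -0.08, at percentile 0.01, with 45 lower and 7 higher, and this list was not tested on recovered libraries. Syt1, a calcium sensor of vesicle release, was at 34185 in overexpression and 36195 in control cortex, and Slc17a7, the main cortical vesicular glutamate transporter gene, at 30449 and 31689. The median of 66 voltage-gated channel genes was -0.09, below all 10000 random lists, with 52 lower. On 9 recovered channel genes camera gave an adjusted p of 0.00969 with the preset correlation, and the adjusted p was 0.73 with an estimated correlation. Scn2a was at 8422 and 9459, and Scn8a at 8674 and 8867. The median of 47 GABAergic and inhibitory synapse genes was -0.08, at percentile 0.01, with Slc12a5 at 10300 and 11014. For 22 upper-layer markers it was -0.09, at percentile 0.05, with Cux2 at 3603 and 3902 and Plxnd1 at 3695 and 3787. The 43 neuropeptide and neuromodulator genes had a median of -0.07, at percentile 0.07, with Chgb at 9448 and 9601 and Chrm1 at 4389 and 4791. The 32 immediate early genes had a median of -0.06, at percentile 1.23, with Egr1 at 6228 and 6782 and Homer1 at 4552 and 4741. With the mean in place of the median, neuropeptide and immediate early genes lay inside the random range, at percentiles 6.26 and 4.86. With an estimated correlation the adjusted p on recovered libraries was 0.73 for neuropeptide, 0.781 for upper-layer, 0.862 for GABAergic and 0.926 for immediate early genes. For the 9 channel genes the recovered median was -0.168 and stayed between -0.118 without overexpression B and -0.187 without overexpression A. Recovered medians of the other tested lists named here depended on single libraries. For 6 upper-layer markers the median was -0.108, but -0.05001 without control B and -0.0105 without overexpression C. For 11 GABAergic genes it was -0.0703, but -0.029 without control A, -0.0187 without control C, -0.0214 without overexpression A and -0.107 without overexpression B. For 25 neuropeptide genes it was -0.0245 and moved by over 1.5 times without any 1 library, to between -0.0887 without overexpression A and 0.00653 without overexpression B. For 12 immediate early genes it was -0.0156 and moved as far without any library but control B, to between -0.0859 without overexpression B and 0.0216 without overexpression C.

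Medians of other neuronal lists lay inside the random range. The 24 deep-layer markers had a median of -0.000365 on the log2 scale, at percentile 75.8, with Tbr1 at 2847 in overexpression and 2946 in control cortex and Bcl11b at 1886 and 1937. Of these 24 genes 12 were higher and 12 lower, and 2 had an unadjusted p under 0.05 in the authors' deposited table. Their share had a Fisher's exact p of 0.0737 adjusted over the 33 lists, and the smallest authors' p adjusted over the list alone was 0.0551. For 16 general excitatory neuron markers the median was -0.05, at percentile 23.9, with Camk2a at 63088 and 66769 and Nrgn at 36893 and 37820, and the mean was -0.117. Of these 16 genes, Neurod6 and Slc17a6 had an unadjusted p under 0.05 in the authors' deposited table, a larger share than among other genes by a two-sided Fisher's exact test (p = 0.0494 adjusted over the 33 lists), which treats genes as independent. Without Neurod6, whose locus carries Nex-Cre, only Slc17a6 would remain, and the share without Neurod6 was not tested. For comparison, 1 of 22 upper-layer markers gave p = 0.706 by the same Fisher's exact test and adjustment. This list was not tested with camera. The median was -0.03 for 65 axon guidance and dendrite adhesion genes, at percentile 13.9, with Cntn1 at 10314 and 10912 and Epha4 at 6623 and 7177. Neurotrophic factors and receptors, 44 in all, had a median of -0.02 at percentile 30.04, with Ntrk2 at 11576 and 12952 and Ntrk3 at 4684 and 4568. The 40 genes tied to autism had a median of -0.05, at percentile 33.2, with Mef2c at 22954 and 26028.

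**Figure D3:**
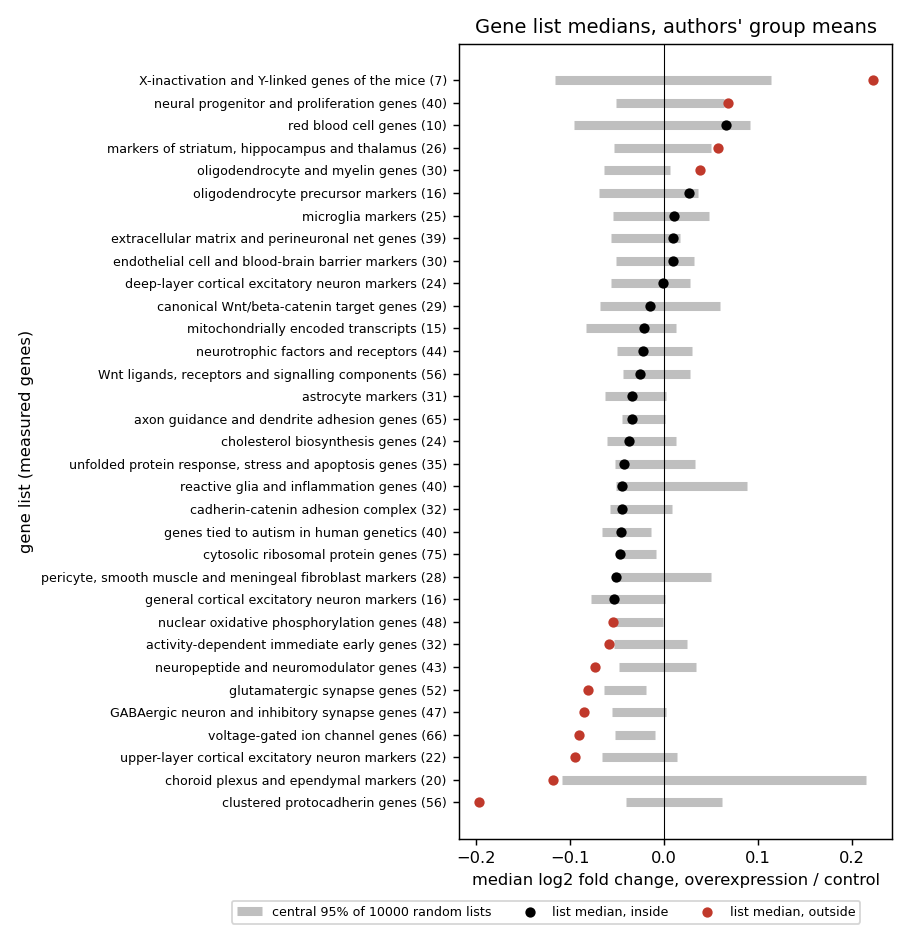
Median log2 fold change of overexpression over control group means (x axis) of the 33 gene lists (y axis, number of measured genes in brackets). Grey bars span the central 95% of 10000 random lists matched on mean expression; 13 medians (red) lie outside, with clustered protocadherins lowest at -0.20.

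Markers of glia and vessels had medians near 0, and 0 members of these lists passed the threshold. The 30 oligodendrocyte and myelin genes had a median of 0.04, at percentile 99.96, with 24 higher and 6 lower. The mean over these genes was 0.0587. On 8 recovered members the median was 0.0135, with an adjusted p of 0.988 with an estimated correlation, and it moved by over 1.5 times without any 1 library, to between -0.109 without overexpression B and 0.17 without overexpression C. Mbp was at 57327 in overexpression and 52980 in control cortex. Oligodendrocyte precursor markers, 16 in all, had a median of 0.03 at percentile 95.6, with Ptprz1 at 5984 and 6170 and Cspg5 at 5744 and 6075. The 31 astrocyte markers had a median of -0.03, at percentile 40.9, with Slc1a2 at 69614 and 72524 and Glul at 20449 and 20799. For 25 microglia markers it was 0.01, at percentile 71.7, with Csf1r at 1639 and 1597 and Cx3cr1 at 1144 and 1104. Reactive glia genes, 40 in all, had a median of -0.04 at percentile 4.015, with Gfap at 2751 and 2711 and B2m at 1080 and 1120. The 30 endothelial markers had a median of 0.01, at percentile 83.5, with Slc16a1 at 2101 and 1952 and Slc2a1 at 1593 and 1644. The 28 mural and meningeal markers had a median of -0.05, at percentile 3.57, with Rgs5 at 4191 and 4207 and Col4a1 at 2988 and 2931. On 18 recovered members their median was -0.112, but 0.221 without overexpression A, -0.23 without overexpression B and -0.311 without overexpression C. The 39 extracellular matrix and perineuronal net genes had a median of 0.01, at percentile 94.2, with Sparcl1 at 30317 and 32004 and Spock2 at 18903 and 20181.

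Markers of neighbouring tissue varied between libraries. The 20 choroid plexus and ependymal markers had a median of -0.12, at percentile 1.85, with Enpp2 at 4916 in overexpression and 5398 in control cortex and Ttr at 122 and 290. The choroid plexus list lay inside the random range over members with a mean of at least 10, with a median of -0.0091 at percentile 30.95, and with the mean in place of the median, at percentile 12.01. On 12 recovered members its median was 0.0213, with an adjusted p of 0.988 with an estimated correlation, and it moved by over 1.5 times without any library but overexpression A, to between -0.126 without control A and 0.213 without control B. The higher Ttr mean came from control library B, whose recovered value was 713, while the other control libraries had 76.4 and 79.4. The 26 markers of striatum, hippocampus and thalamus had a median of 0.06, at percentile 98.6, with Pde10a at 2256 and 2303. Its percentile was 96.86 with the mean in place of the median, and on 15 recovered members the adjusted p was 0.988 with an estimated correlation. Their recovered median was 0.0578 and moved by over 1.5 times without any library but control C, to between -0.0449 without overexpression C and 0.203 without overexpression B. Red blood cell genes, 10 measured, had a median of 0.07 at percentile 93.9, with Hbb-bs at 1694 and 1639. The 40 progenitor and proliferation genes had a median of 0.07, at percentile 98.2, with Tubb3 at 9019 and 8895 and Dpysl3 at 2891 and 2737. On 29 recovered members the adjusted p was 0.82 with an estimated correlation. Their recovered median was 0.0634, but 0.181 without control B, 0.124 without overexpression A and 0.177 without overexpression B. Of the 7 sex-linked genes, the 6 detected in both groups had a median of 0.22, at percentile 99.9, with Xist at 7657 and 7626 and Eif2s3y at 488.6 and 391.99. The sex-linked list lay at percentile 89.96 with the mean in place of the median and was not tested on recovered libraries. Nearly all reads of the Y-linked genes Eif2s3y, Kdm5d and Ddx3y, the last 2 named after their values were seen, came from 1 library in each group. For Uty, also Y-linked, this held in control cortex, and no such combination was found for its overexpression mean of 137.

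The lowest median belonged to the clustered protocadherins, cell-surface adhesion genes expressed in neuron-specific combinations. It was -0.20 over 56 genes, below all 10000 random lists, with 48 lower and 8 higher and 0 past the threshold. Pcdhgc5 was at 2089 in overexpression and 2334 in control cortex, and Pcdhac2 at 779 and 931. These genes share constant exons within a cluster, so the split of reads among them is uncertain. For 51 recovered members camera with the preset correlation gave p = 9e-10 adjusted over 25 lists, and the adjusted p was 0.73 with an estimated correlation. The recovered median was -0.22, but -0.01 without overexpression library B and -0.34 without overexpression library C.

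Lists of general cell functions differed little. The 48 nuclear oxidative phosphorylation genes had a median of -0.05, at percentile 1.62, with 43 lower, among them Atp5b at 15438 in overexpression and 17187 in control cortex and Atp5a1 at 13323 and 13945; this list was not tested on recovered libraries. The 75 ribosomal protein genes had a median of -0.05, at percentile 3.38, with Rpsa at 6600 and 6926 and Rpl4 at 5726 and 6088. For the 14 of 15 mitochondrially encoded transcripts detected in both groups it was -0.02, at percentile 70.6, with mt-Co1 at 293037 and 316141 and mt-Cytb at 117120 and 120021. The 24 cholesterol biosynthesis genes had a median of -0.04, at percentile 23.8, with Hmgcs1 at 10889 and 10980 and Srebf2 at 4679 and 5048. Stress and apoptosis genes, 35 in all, had a median of -0.04 at percentile 6.19, with Calr at 9223 and 9470 and Hsph1 at 5807 and 6188.

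In all, 13 of the 33 list medians lay outside the central 95% of random lists, 9 below and 4 above, where 1.65 would be expected if genes varied independently. With the share of random lists adjusted over the 33 lists, 8 of the 13 stayed under 0.05, and the adjusted share was 0.0898 for immediate early genes and markers of other regions and 0.0939 for choroid plexus, progenitor and oxidative phosphorylation genes. The sex-linked list was among the 8, at 0.0074, although Eif2s3y, Kdm5d and Ddx3y drew nearly all their reads from 1 library in each group. Random lists ignore that the genes of a list vary together between libraries. On recovered libraries 2 of 25 lists passed with camera's preset correlation, the clustered protocadherins and the voltage-gated channels. With an estimated correlation 0 lists passed, the smallest adjusted p was 0.73, and fry also gave 0 lists, with a smallest adjusted p of 0.961.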

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

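All settings on recovered libraries were chosen after seeing the data. No paired analysis was possible because the deposited table held group means and the recovered libraries carry no replicate number. Other alternatives planned for per-library counts were not run on the table as deposited, namely another count test, another normalization and camera with the replicate block, and no library was left out for Ctnnb1, which was not recovered.

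The counts of 0 genes higher and 0 genes lower held at a mean of at least 10, at an adjusted p under 0.01, with a log2 fold change of at least 1, with the adjustment recomputed over all genes or over those with a mean of at least 10, and with centring. On recovered libraries limma gave 0 genes in each direction with a pseudocount of 1 or 0.1, a mean of at least 1, 10 or 100, the sex of the library as a term, and each of the 6 libraries left out. With no filter it called 1 gene as higher, mt-Tp (adjusted p = 0.0205; smallest adjusted p in the other fits between 0.251 and 0.9998), and the cause was not tested. The number of genes with an unadjusted p under 0.05 was 207 and ranged from 150 to 368 with a library left out, the highest values being 368 without control library C, 323 without overexpression library B and 311 without overexpression library C. It was 68 at a mean of at least 100, 441 at a mean of at least 1 and 706 with no filter, as the number of genes tested changed.

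The log2 fold change of Ctnnb1 stayed at -0.24 or -0.25 under centring and the 3 pseudocounts. The number of lists outside the random range was 13 and stayed within 1.5 times of that with a pseudocount, centring, the filter, the mean, and matching on exon length. It was 2 with Fisher's exact test on the authors' unadjusted p, 2 with camera's preset correlation, and 0 with an estimated correlation, fry, and fry for either direction, where 25 lists were tested in place of 33. Among 248 alternatives for 62 single genes, 1 changed sign, Rgs5 under centring to 0.00343. The log2 fold change of Gm3279, whose control mean was 2.53, fell from 2.93 to 2.52 with a pseudocount of 1 and to 1.23 with a pseudocount of 10. Leaving out 1 library turned the sign of 16 of 25 recovered list medians, 5 of them among the 10 such lists whose median over the deposited group means lay outside the random range. These 5 ranged from -0.0859 (without overexpression B) to 0.0216 (without overexpression C; 0.0184 without control A) for immediate early genes, from -0.0887 to 0.00653 (without overexpression B) for neuropeptides, from -0.109 (without overexpression B; -0.0278 and -0.00638 without control C and A) to 0.17 for oligodendrocytes, from -0.126 (without control A; -0.0583 without overexpression C) to 0.213 for choroid plexus, and from -0.0449 (without overexpression C) to 0.203 for other regions. The mean had another sign than the median for deep-layer markers (0.03), neurotrophic genes (0.01) and stress genes (0.01), none of them outside the random range. Among other lists inside the range, the mean was -0.00987 for reactive glia (median -0.0444) and 0.214 for red blood cell genes (median 0.0659). It was 0.0393 for extracellular matrix genes (median 0.00985) and -0.0565 for mitochondrially encoded transcripts (median -0.0211). The recovery limits these fits to genes with a mean of up to 450 in overexpression cortex. Simulated 1.5-fold changes were called for 46.7% of genes, and the share may be smaller in these data, whose libraries also share variation.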

Other observations

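All tests in this part were chosen after the results were seen. Most Y-linked reads of each group came from 1 recovered library, as if both sexes were present in each group. Reads of Kdm5d, a Y-linked histone demethylase gene, came to 658 in control library A and 0 in the other 2 control libraries, and to 1000 in overexpression library A and 0 in the other 2. Eif2s3y gave 1155 and 1799 reads in the same libraries and 0 elsewhere. Uty did not show this in both groups, as no combination with all but 5 reads in 1 library gave its overexpression mean. A combination with all but 5 reads in 1 library was found for 5 of 4844 control values and 3 of 4874 overexpression values between 100 and 500. These counts include Kdm5d, Ddx3y and Eif2s3y in both groups and Uty in control cortex, so even fewer other genes show it. With the sex of the library as a term, limma again called 0 genes, with 230 at an unadjusted p under 0.05.

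The 2 genes with the smallest p in the authors' deposited table, Gm3279 and Neurod6, are direct neighbours among expressed genes in the reference annotation, and the chance of this for a random pair is 6.83e-05. A loss of excitatory neurons is argued against, because the 15 other excitatory neuron markers had a median log2 fold change of -0.0493 (SD 0.125 between genes), far from the -0.70 of Neurod6. The Cre allele at this locus may itself lower Neurod6 and raise its neighbour, but Cre and stabilised β-catenin came together in the 3 overexpression libraries and cannot be told apart without a Cre-only group. A segment of another strain linked to the Cre allele also stays open, since 1 of the 40 nearest other expressed genes had an unadjusted p under 0.05 against 0.525% of other genes (two-sided Fisher's exact p = 0.191). An effect of β-catenin on Neurod6 transcription was not tested.

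The 13 list medians outside the random range are a second pattern. Exon length as the cause is argued against, because 12 of the 13 stayed outside when random lists were matched on it as well, and choroid plexus markers did not. Gene length with introns was not tested. In the recovered libraries the real grouping put 5 of 25 lists outside and the other splits up to 12, with 10 of 10 splits giving as many as the real one. With 10 splits of 6 libraries no share under 0.05 can be had. A difference between genotypes in these lists stays open, as 0 of the 10 that could be tested on recovered libraries passed by camera with an estimated correlation or by fry, which does not show that they were equal, and the glutamatergic synapse, oxidative phosphorylation and sex-linked lists were not tested there.

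Variation between the recovered libraries did not follow genotype. The first principal component held 28.4% of the variance and did not separate the groups. Among the genes with the largest loadings, Lhx9, C1ql2, Gpr101, Lct and Ndst4 were lowest in control C and overexpression B. A large loading brings this with it, so these genes are not a test. A candidate explanation is a differing amount of hippocampal tissue in the dissections. Other regions such as thalamus were not tested in this way. Of 17 group values of 9 hippocampal markers not used to find the pattern, 15 were lowest in those 2 libraries, where 5.67 would be expected (exact binomial p = 4.48e-06, one-sided, although genes are not independent), among them Bok, Spink8 and Iyd; cortex expresses some of these genes too. Whether striatal tissue followed the same 2 libraries cannot be told. Of 8 group values of striatal markers, 4 were highest and 1 was lowest in those 2 libraries, where 2.67 would be expected (exact binomial p = 0.259 for more than chance and 0.912 for fewer, each one-sided), so the test decides neither way. Those 4 were control values, and all 5 control values were lowest in control A. The control libraries thus did differ in striatal markers. Adora2a was at 108 in control A against 267 and 287 in control B and C, and Gpr6 at 81.5 against 108 and 97.1. No biological explanation was tested because the component does not follow genotype.

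The count of genes with an unadjusted p under 0.05 on recovered libraries was compared with the other ways of dividing the 6 libraries into 3 and 3. The real grouping gave 207 genes and the highest other split 787, and 9 of the 10 splits gave as many as the real one. With 10 splits no share under 0.05 can be had. The split with 787 genes set control A, control B and overexpression A against the rest. Groups did not overlap for 699 of 9781 genes, or 7.15%, where chance gives 10%.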
